A study of Dorcoceras hygrometricum with 24 samples.

How the data were processed

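Leaves of the resurrection plant Boea hygrometrica, listed in the labels as Dorcoceras hygrometricum, were profiled on 24 one-colour oligonucleotide arrays, 3 for each of 8 groups. A resurrection plant is one whose leaves can lose nearly all their water and recover on rewatering. Total RNA was amplified, labelled with the dye Cy3 and hybridised, 1 sample per array. Each array carried 15553 spots, of which 15017 were not controls. Those spots held 14567 probes of 60 bases, 14517 of them spotted once and 50 spotted 10 times.

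The scanner files hold spot intensity values on a linear scale, made with Agilent Feature Extraction 10.7.1.1 per the submitters' processing notes. Per the file headers, the processed signal intensity is background-subtracted, with a surrogate value in place of signals that did not exceed background. A table of the whole series was also deposited, in log2 units. Set against the scanner intensities, each of its 24 columns was closest in rank to the raw mean signal of its own array. Its column medians lay between 8.96 and 8.98. Its scale is thus log2 without centring of probes, and it follows the signal before background subtraction. The exact normalization is not given in the sources used here; limma is named in the submitters' processing notes without a version or a role.

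No file pairs a probe with a gene. All 14567 probes carry no gene name or description and no genome position, no genome comes with the series, and no gene was named from a sequence. The 26 gene lists fixed before the data were examined therefore matched 0 probes, and no list was tested. Probes are given by the identifier in the files. The rule set before the data were examined for this case names the 2 probes with the largest rise and the 2 with the largest fall, for comparisons against control, comparisons of acclimated with fresh plants and differences of responses. Its wording for named genes asks for an adjusted p below 0.05 and no overlap between the replicates compared. The first condition was applied to all named probes. The second was applied where 2 groups were compared, not to the differences of responses. A further condition, that the probe is well above background on every array of the groups compared, was added after the data were examined. The rule was extended in the same form to the comparisons with rehydrated plants and of slow with rapid drying. One transcript can be represented by several probes: 325 of the 14567 probes share their sequence with another one, so counts are of probes, not of genes.

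For the tests, log2 of the processed signal was averaged over the spots of a probe, leaving out flagged outlier spots, and each array's 75th percentile was subtracted. A level below is this log2 value. Probes were kept if they were well above background, by the scanner software's own flag, on all 3 arrays of at least 1 group, which left 11646. The arrays were fitted together, with 8 group means and 16 residual degrees of freedom per probe, by the moderated test of limma 3.58.1 in R 4.3.3. A probe was called changed at a Benjamini-Hochberg adjusted p below 0.05, two-sided. In all, 14 contrasts were tested. They were each of the 7 treated groups against control, both acclimated dried groups against rehydrated plants, both acclimated dried groups against the fresh groups dried for the same time, slow against rapid drying, and the difference between the acclimated and the fresh response at 2 h and at 48 h. All fold changes are relative to the 75th percentile of an array, so a change in the total amount of messenger RNA per leaf cannot be seen.

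Where a probe was not well above background on any array of a group, its fold is given as a lower bound. The bright group's mean was set against the mean, over the dim arrays, of the higher of the dim signal and the lowest signal among probes well above background on that array.

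Signal over background sets the depth of these data. The median signal per array lay between 356 and 570 units, and 55.4% to 83.5% of probes were well above background. The 24 arrays sat on 3 slides in 2 rows of 4. On the 12 arrays of the first row, 77 negative-control spots had a standard deviation (SD) of 2.30 to 5.22 units, and 70.5% to 83.5% of probes were detected. On the 12 arrays of the second row the SD was 4.45 to 57.5 units and 55.4% to 68.9% were detected. Slide 1 held the 3 control arrays, the 3 fresh 2 h arrays and 2 fresh 48 h arrays. Slide 2 held the third fresh 48 h array, both slow-drying groups and 1 rehydrated array. Slide 3 held 2 rehydrated arrays and both acclimated dried groups. The 3 slow 14 d and the 3 acclimated 48 h arrays lay in the second row, and the 3 control and the 3 slow 5 d arrays in the first. Slide and row were used as blocks in alternative fits, which rest on the groups that span slides or rows. Only 1 fresh 48 h array links slide 2 with slide 1, and only 1 rehydrated array links slide 2 with slide 3. The series design states 3 biological replicates per group; the labels do not say how plants were assigned to arrays. With 3 arrays per group, the number of arrays limits the precision of every value.

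Alternatives covered the background correction (normexp with an offset of 50), the scaling (quantile, median, spike-in spots), the deposited log2 values and the filter on dim probes. They also covered the arrays in the fit, slide as a fixed or random block, the replicate number as a block, stricter thresholds (2-fold, adjusted p below 0.01) and leaving out each array in turn. Blocks for the slide row, fits within a row or slide, and a common floor on the signal were added after the data were examined. The test was checked on simulated arrays with 10780 probes and 50 probes changed at each of 4 sizes. Each probe had the same spread in every group, pooled from the observed arrays, as the fit assumes. A larger spread in some groups, such as that of the fresh 48 h arrays, was not simulated. The shares of false calls below do not cover it. For fresh 2 h against control, 45 of 50 probes changed 8-fold were recovered, 40 of 50 changed 4-fold, 18 of 50 changed 2-fold and 10 of 50 changed 1.5-fold, and 5.04% of calls were false. For the difference between the 48 h responses the recovered numbers were 38, 31, 19 and 3 of 50, and 4.21% of calls were false. The recovery first aimed for at 8-fold was not reached for that difference, and the simulation was then judged by the size of the fitted folds, the share of false calls and agreement with limma. Small changes are therefore undercounted.

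A pair of summary scores, defined like the other summaries of probe groups after the counts of changed probes had been seen, places each array on the drying responses. The rapid-drying score is the mean level over the 6183 probes changed in fresh plants dried for 48 h, each with the sign of that change, scaled so that the control mean is 0 and the fresh 48 h mean is 1. The slow-drying score uses the 6822 probes changed after 14 d of slow drying in the same way. Scores were compared with exact permutation tests, two-sided, which with 3 arrays against 3 cannot give a p below 0.1. Because the probes and signs of both scores come from comparisons with the same control arrays, rehydrated plants were set beside 20 simulations of unchanged plants, and the scores were repeated with 1 control array as the baseline and the others for choosing probes and signs. The position of acclimated 48 h plants between fresh 48 h and slow 14 d plants is a cross-product of their differences from fresh 48 h arrays, with no array used in both differences. Overlaps between comparisons that share the control arrays were set beside 20 simulations of unchanged groups against the same controls. Only noise entered these, so almost no probe is called in them and shared calls near 0 follow by construction. Their correlation near 0.50 also holds for noise alone, so real correlations are not measured against it. Their covariance shows what shared controls add. The 3 control arrays are too few to be split into 2 sets of 2, so part of an overlap may come from the shared controls. Figures were drawn with matplotlib 3.10.9.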

Results

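The series measured transcript levels in leaves of the resurrection plant Boea hygrometrica in 8 states of water supply, with 3 arrays each. Control plants were watered. Fresh plants, which had not been dried before, were taken from the soil and dried rapidly for 2 h, to a relative water content (RWC) of about 80%, or for 48 h, to under 10%. Slowly dried plants stayed in their pots without water for 5 d (about 80% RWC) or 14 d (under 10%). Rehydrated plants were dried slowly for 14 d and watered again for 3 d. Acclimated plants had gone through that cycle of slow drying and rewatering and were then dried rapidly for 2 h or 48 h to the same nominal water contents. The comparisons ask how leaf transcripts follow rapid and slow drying, and how an earlier drying cycle alters the response to rapid drying.

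Of 14567 probes, 11646 were tested, and 6945 were well above background on all 24 arrays. Over the 6945 probes, arrays of 1 group correlated at 0.94 to 0.99 (Pearson's r across probes, which are not independent replicates). Fresh plants dried for 48 h were the most variable group, with a median SD per probe of 0.34 on the log2 scale, against 0.13 in control and 0.16 to 0.22 in the 6 other groups. The first principal component held 44.4% of the variance and the second 25.6%. No probe is paired with a gene in the files, so the probes below are given by their identifiers, with levels as log2 signal relative to the 75th percentile of the array.

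**Figure D1:**
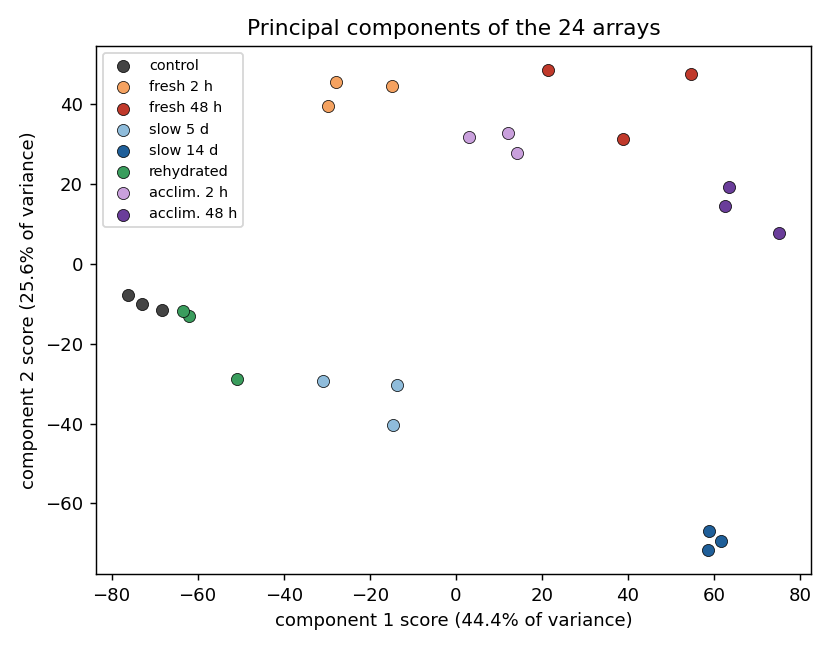
Scores of the 24 arrays on principal component 1 (x axis, 44.4% of the variance) and component 2 (y axis, 25.6%), both in arbitrary log2 units, 1 point per array, coloured by group. Fresh 48 h arrays are spread from 21.5 to 54.8 on component 1, with replicate 3 nearer in this plane to an acclimated 2 h array than to its own group. Rehydrated replicate 2 lies nearer to a slow 5 d array than to control in this plane only. On component 3 (10.6%, not drawn) it lies at -0.86, control at 19.8 to 22.0 and slow 5 d at -58.0 to -49.8.

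Rapid drying of fresh plants for 2 h raised 2134 probes and lowered 2265, together 4399 of the 11646 tested, and 1470 rises and 974 falls were at least 2-fold. The changes were large for some transcripts. CUST_13658_PI425357171 rose 237-fold, from a level of -6.26 ± 0.60 (SD, n = 3) in control to 1.63 ± 1.11, a log2 change of 7.89 with a standard error (SE) of 0.65 (adjusted p = 7.37e-08, limma). Its sequence is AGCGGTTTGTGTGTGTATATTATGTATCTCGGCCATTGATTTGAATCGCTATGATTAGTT. CUST_14555_PI425357171 rose 82.7-fold, from -2.43 ± 0.63 to 3.94 ± 0.55. CUST_13846_PI425357171 and CUST_12746_PI425357171, which carry the same 60 bases, fell from 2.43 ± 0.14 and 2.51 ± 0.08, with log2 changes of -4.17 (SE 0.53) and -4.10 (SE 0.51). Among the raised probes, 10 were not well above background in any control array but were measured on all 3 fresh 2 h arrays. The most changed of them was at least 195-fold higher. Of the probes measured in control, 529 were not well above background on any fresh 2 h array. Only 3 of them were called with a lower bound on the fall of at least 2-fold. How far the others fell is not known. Of the fresh 2 h arrays, 2 lay in the second slide row, where fewer probes were detected. The share of rises among the changed probes, 48.5%, was 38.4% with scaling on spike-in spots and 37.7% with the deposited log2 values. With slide as a block 4449 probes were called, and 3864 when the arrays of slide 1, which held all 6 arrays, were fitted alone. With row as a block 3644 were called, and with slide and row 3430.

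After 48 h of rapid drying, to under 10% RWC, 2895 probes were higher than in control and 3288 were lower, and 4086 of these 6183 differed at least 2-fold. Of the 6183, 5208 were well above background on every control and fresh 48 h array. Of the probes raised at 2 h, 1668 were still raised at 48 h and 24 were lowered; of those lowered at 2 h, 1825 were still lowered and 45 were raised. Against the 3493 probes changed the same way at both times, independent lists would share 530 rises and 639 falls. Simulations of unchanged groups against the same controls shared 0, which follows from their having almost no calls. The covariance of the log2 changes was 1.42 against 0.11 simulated. Their correlation across probes was r = 0.78, and the 0.50 simulated holds for noise alone. CUST_13658_PI425357171 rose further, to 4.89 ± 0.72, which is 2273-fold over control (log2 change 11.15, SE 0.65, adjusted p = 2.44e-10). CUST_12631_PI425357171 rose 1863-fold, from -6.55 ± 0.67 to 4.31 ± 0.62. CUST_2_PI425357171 and CUST_1386_PI425357171 fell, with log2 changes of -5.74 (SE 1.68) and -5.09 (SE 0.54). The first of these was not called with slide and slide row as blocks (log2 change -4.02, adjusted p = 0.258). The number of probes switched on from below background was 38, with bounds of up to 2141-fold. Of the probes measured in control, 363 were not well above background on any fresh 48 h array. Only 4 of them were called with a lower bound on the fall of at least 2-fold. How far the others fell is not known. Of the fresh 48 h arrays, 2 lay in the second slide row, where fewer probes were detected. Rises made up 46.8% of the changed probes, and 60.2% with normexp background correction, which moved the median log2 change of all probes from -0.11 to 0.36. Slide 1 alone gave 5649 changed probes, and slide as a block 5902. With row as a block the count was 5723, and with slide and row 4710.

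**Figure D2:**
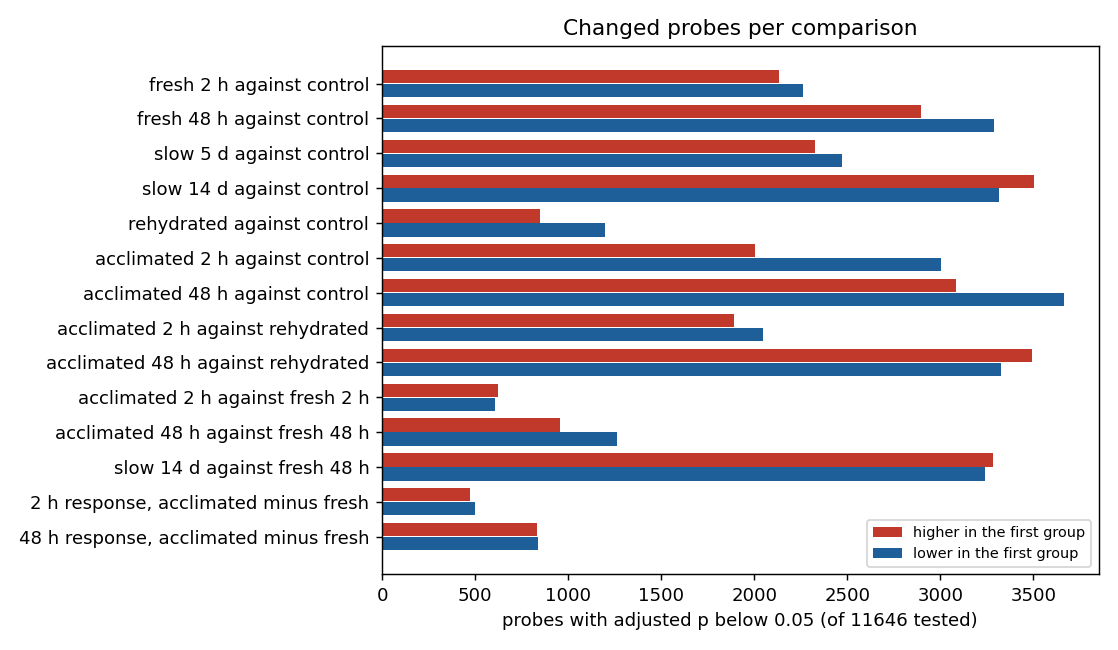
Number of probes with an adjusted p below 0.05 (x axis, of 11646 tested) that were higher (red) or lower (blue) in the first-named group of each of the 14 comparisons (y axis). The fewest probes changed in the difference of the 2 h responses (971) and counts reached 6822 in slow 14 d plants against control.

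Slow drying in the pot for 5 d, to about 80% RWC, raised 2328 probes and lowered 2470. CUST_3350_PI425357171 rose 136-fold, from -7.05 ± 0.65 to 0.04 ± 0.26, and CUST_13732_PI425357171 rose by 6.66 on the log2 scale, from -4.55 ± 1.35 to 2.10 ± 1.07. CUST_13163_PI425357171 fell from 3.89 ± 0.10 to -4.75 ± 2.43, a log2 change of -8.65 with an SE of 1.35 (adjusted p = 5.94e-05), and CUST_184_PI425357171 fell from 2.95 ± 0.11 to -5.30 ± 1.86, a call that was lost with slide and slide row as blocks (log2 change -6.26, adjusted p = 0.138). Rises were 48.5% of the changed probes and 71.7% with spike-in scaling. Control and slow-dried arrays were on different slides, both in the first slide row; with slide as a block 2998 probes were called, against 4798 without, and with slide and row 2611.

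Slow drying for 14 d, to under 10% RWC, changed 6822 probes, 3504 higher and 3318 lower, and 4759 of them at least 2-fold. CUST_12877_PI425357171 rose from -6.58 ± 0.58 to 5.20 ± 0.05, which is 3521-fold (log2 change 11.78, SE 0.44, adjusted p = 4.70e-13). Its sequence is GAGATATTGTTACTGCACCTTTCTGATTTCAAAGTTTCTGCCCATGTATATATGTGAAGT. CUST_734_PI425357171, whose sequence is on 3 probes and shares 37 bases with that of CUST_12631_PI425357171, rose 3167-fold. CUST_13593_PI425357171 fell from 5.92 ± 0.22 to -3.43 ± 0.83, and CUST_14274_PI425357171 from 6.36 ± 0.19 to -2.43 ± 0.92, log2 changes of -9.35 (SE 0.47) and -8.78 (SE 0.50). Of the probes raised at 5 d, 1388 were also raised at 14 d and 310 were lowered; of those lowered at 5 d, 1415 were also lowered and 331 were raised. Independent lists would share 700 rises and 704 falls, and simulated unchanged groups, which have almost no calls, shared 0.05 on average. The covariance of the changes was 1.55 against 0.10 simulated. The correlation across probes was 0.57, and the 0.50 simulated holds for noise alone. Among the raised probes, 23 were switched on, with bounds of up to 2914-fold. Of the probes measured in control, 1999 were switched off. Of these, 382 were called with a lower bound on the fall of at least 2-fold, and how far the others fell is not known. The second slide row detected fewer probes, which enters the number switched off. Rises were 51.4% of the changed probes and 62.9% with spike-in scaling. All slow 14 d arrays lay in the second slide row and all control arrays in the first; the count was 5045 with slide, 6046 with row, and 3496 with both as blocks.

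Both ways of drying to under 10% RWC shared much of their response, but not all of it. Of the probes changed in fresh 48 h and in slow 14 d plants, 1757 were raised by both, 1698 were lowered by both, and 807 went opposite ways. Independent lists would share 871 rises and 937 falls, and simulated unchanged groups, which have almost no calls, shared 0. The covariance of the changes was 1.93 against 0.11 simulated. The correlation was 0.57, and the 0.50 simulated holds for noise alone. Compared directly, 3285 probes were higher and 3241 lower after 14 d of slow drying than after 48 h of rapid drying. CUST_4907_PI425357171 was 137-fold higher after slow drying (3.13 ± 0.27 against -3.97 ± 1.19) and CUST_11442_PI425357171 98.0-fold higher. CUST_2090_PI425357171 was at -4.19 ± 0.31 after slow drying and at 4.18 ± 0.48 after rapid drying, a log2 difference of -8.37 with an SE of 0.40 (adjusted p = 1.54e-11), while control lay at 3.63 ± 0.32. CUST_13593_PI425357171 was also lower after slow drying, by a log2 difference of -7.57. The 50.3% of calls that were higher after slow drying became 37.6% with normexp background correction and 63.8% with spike-in scaling. The count was 5354 with slide as a block, within slide 2 alone (with 1 fresh 48 h array, assumed to vary like the other groups) 5128, and within the second slide row 4915.

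Most of the slow-drying response was no longer called after 3 d of rewatering. Of the 3504 probes raised at 14 d, 2814 (80.3%) were not called in rehydrated plants against control, 504 were still higher and 186 were lower. Of the 3318 lowered, 2606 (78.5%) were not called, 586 were still lower and 126 were higher. Of all 11646 tested probes, only 17.6% were called in rehydrated plants. Most probes thus went without a call whatever their slow-drying change, and these shares do not measure reversal. With slide as a block, 25 of the 2425 probes then raised were still higher and 52 of the 2620 lowered were still lower, and 0 went the opposite way. A probe without a call is not shown to be back at the control level. Over the raised probes the median log2 change against control was 1.24 at 14 d and 0.11 after rewatering; over the lowered probes it was -1.84 and -0.37.

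Rehydrated plants differed from control at 847 higher and 1200 lower probes. CUST_13392_PI425357171 and CUST_14370_PI425357171, which share 1 sequence with CUST_12650_PI425357171, were 231-fold and 223-fold higher. The sequence is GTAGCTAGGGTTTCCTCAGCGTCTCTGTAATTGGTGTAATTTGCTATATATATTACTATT. The level of CUST_13392_PI425357171 was -2.42 ± 2.71 in control, 6.42 ± 0.01 after 14 d of slow drying, and 5.43 ± 1.18 after rewatering (log2 change from control 7.85, SE 0.90, adjusted p = 2.55e-05). CUST_7827_PI425357171 and CUST_5863_PI425357171 were lower, with log2 changes of -4.11 (SE 1.30, adjusted p = 0.0372) and -3.58 (SE 0.87, adjusted p = 0.00942). Without rehydrated replicate 2 these were -2.18 and -2.50 and neither was called (adjusted p = 0.207 and 0.0595), and the call of the first was also lost without any 1 of the control arrays or rehydrated replicate 3, at log2 changes of -3.94 to -4.42. The comparison crosses slides, and with slide as a block 86 probes were called, against 2047 without, and with slide and row 31. None of the 4 named probes was called in either fit, but only the change of CUST_5863_PI425357171 shrank, to -1.98 with slide and -1.09 with slide and row. The log2 changes in these fits were 7.89 (adjusted p = 0.0675) and 9.39 for CUST_13392_PI425357171, 7.96 and 9.36 for CUST_14370_PI425357171, and -4.14 and -5.36 for CUST_7827_PI425357171. Slide as a random block, which also uses differences between slides, gave 1541 calls. Within the first slide row, which held the 3 control and 2 of the rehydrated arrays, 3405 probes were called. The count fell to 1196, 1221 and 1137 without control replicate 1, 2 or 3, and to 1139 without rehydrated replicate 2.

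**Figure D3:**
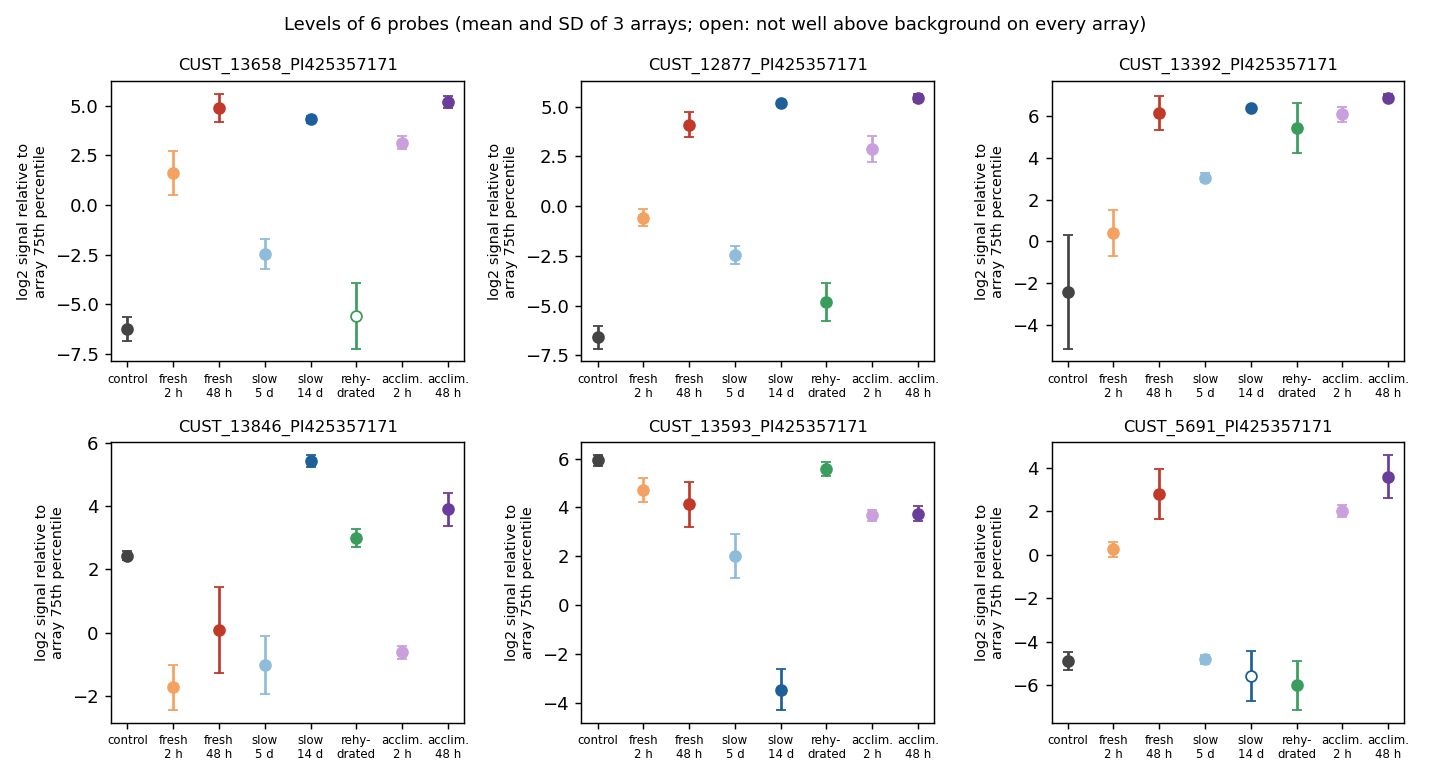
Levels of 6 named probes, 1 panel each, as log2 signal relative to the array's 75th percentile (y axis) in the 8 groups (x axis); points are means and bars SDs of 3 arrays, and open points mark groups in which the probe was not well above background on every array. CUST_13392_PI425357171 stayed at 5.43 after rewatering, while CUST_12877_PI425357171 lay at -4.81 there and at 5.20 after 14 d of slow drying.

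Acclimated plants dried rapidly for 2 h had 1893 probes higher and 2050 lower than the rehydrated plants they started from. CUST_4207_PI425357171 rose 497-fold, from -4.79 ± 0.66 to 4.17 ± 0.17, and CUST_5691_PI425357171 rose by 8.03 on the log2 scale, from -6.01 ± 1.13 to 2.02 ± 0.26. CUST_12888_PI425357171 and CUST_14329_PI425357171 fell, with log2 changes of -5.16 (SE 0.84) and -5.02 (SE 0.73). Rises were 48.0% of the changed probes, 72.6% with spike-in scaling and 36.2% with the deposited log2 values. Slide as a block gave 3562 calls, slide 3 alone 2868, the first slide row alone 4308 and the second, with 1 array of each group, 650, of which 553 were higher and 97 lower.

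After 48 h, 3492 probes were higher and 3328 lower than in rehydrated plants. CUST_12877_PI425357171 rose 1219-fold, to 5.45 ± 0.20, and CUST_4207_PI425357171 993-fold, to 5.17 ± 0.13. CUST_8222_PI425357171 and CUST_12888_PI425357171 fell, with log2 changes of -6.25 (SE 0.71) and -5.97 (SE 0.84). Rises were 51.2% of the calls, 38.7% with quantile normalization and 39.2% with the deposited values. Slide as a block gave 6390 calls, slide 3 alone 5741, and the second slide row alone, with 1 rehydrated array, 3615.

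Against the watered control, acclimated plants differed at 5007 probes after 2 h (2005 higher, 3002 lower) and at 6753 after 48 h (3086 higher, 3667 lower). Of these, 4170 at 2 h and 5264 at 48 h were well above background on every array compared. At 2 h CUST_12877_PI425357171 was 700-fold and CUST_13658_PI425357171 678-fold higher than in control, whereas CUST_13163_PI425357171 and CUST_12613_PI425357171 were lower, with log2 changes of -5.27 (SE 1.35) and -4.41 (SE 0.41). The first of these was -8.23 with slide as a block and no longer called (adjusted p = 0.0513). At 48 h CUST_12877_PI425357171 was 4167-fold and CUST_734_PI425357171 3558-fold higher, and CUST_8222_PI425357171 and CUST_7581_PI425357171 were lower, with log2 changes of -6.84 (SE 0.71) and -6.32 (SE 0.45). With slide and row as blocks the former was -8.31 and not called (adjusted p = 0.0792). Probes changed the same way in fresh and in acclimated plants numbered 3241 at 2 h, with 10 opposite, and 5067 at 48 h, with 52 opposite. Simulated unchanged groups, which have almost no calls, shared 0.05 and 0. Independent lists would share 367 rises and 584 falls at 2 h, and 767 rises and 1035 falls at 48 h. The covariance was 1.22 at 2 h and 2.70 at 48 h, against 0.10 and 0.11 simulated. The correlation was 0.80 and 0.90, and the 0.49 and 0.50 simulated hold for noise alone. At 2 h rises were the smaller part of the calls, but 55.5% of them with spike-in scaling. At 48 h they were 45.7%, but 51.8% with median scaling and 37.7% with quantile normalization, and without the filter on dim probes 4709 were higher and 3612 lower. Fits with slide as a block called 1353 probes at 2 h and 3357 at 48 h, and with slide and row 941 and 1706. These fits turned the balance of calls, to 716 higher and 637 lower at 2 h with slide, and with slide and row to 621 higher and 320 lower at 2 h and 993 higher and 713 lower at 48 h.

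Set directly against fresh plants dried for the same time, acclimated plants had 624 probes higher and 608 lower at 2 h. CUST_14370_PI425357171 was 53.1-fold and CUST_13392_PI425357171 51.7-fold higher (6.09 ± 0.36 against 0.40 ± 1.09 for the latter). CUST_5407_PI425357171 was lower, by a log2 difference of -2.98 (SE 0.46), and so was CUST_12276_PI425357171, by -2.95 (SE 0.77). A fit with slide as a block called 82 probes, against 1232 without, and with slide and row 331. None of the 4 named probes was called in either. Their log2 differences with slide, and with slide and row, were about as large or larger. They were 6.17 and 7.33 for CUST_14370_PI425357171, 5.97 (adjusted p = 0.207) and 7.22 for CUST_13392_PI425357171, -2.86 and -3.61 for CUST_5407_PI425357171, and -4.62 and -5.24 for CUST_12276_PI425357171. Slide as a random block, which also uses differences between slides, called 839 probes. CUST_12276_PI425357171 also lost its call without fresh 2 h replicate 2 or 3 or acclimated 2 h replicate 1 or 2 (log2 difference -2.75 to -3.05, adjusted p = 0.0547 to 0.0708). The first slide row alone gave 239 calls and the second 171, and leaving out 1 array gave 583 and 700 without fresh 2 h replicate 2 or 3 and 729 and 604 without acclimated 2 h replicate 1 or 2. Rises were 50.6% of the calls and 88.7% with spike-in scaling.

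At 48 h, 955 probes were higher and 1265 lower in acclimated than in fresh plants. CUST_10729_PI425357171 was 24.2-fold higher, with an SE of 1.42 on a log2 difference of 4.60 (adjusted p = 0.0302; 0.0513 with normexp background correction), and CUST_13846_PI425357171 was 14.1-fold higher, at 3.90 ± 0.53 against 0.08 ± 1.37. CUST_8795_PI425357171 and CUST_3354_PI425357171 were lower, by log2 differences of -3.39 (SE 0.42) and -3.37 (SE 0.49). Rises were 43.0% of the calls, 27.5% with normexp background correction and 53.6% with median scaling. CUST_10729_PI425357171 lost its call in 5 of the 6 fits without 1 array, where its log2 difference was 3.95 to 4.86. Under the slide block it and CUST_8795_PI425357171 were not called, at log2 differences of 3.05 and -3.19 (adjusted p = 0.666 and 0.0717). With slide and row none of the 4 was called, at 0.97 for CUST_10729_PI425357171, 5.51 for CUST_13846_PI425357171, -2.97 for CUST_8795_PI425357171 and -5.47 for CUST_3354_PI425357171. The count of 2220 was 372 with slide as a block, 97 with slide and row, 211 within the second slide row, and 109 when the 6 arrays were fitted without the other groups. With slide as a random block, which also uses differences between slides, the count was 1751. It was 1262 without fresh 48 h replicate 3 and 1392 without acclimated 48 h replicate 3, and with slide and row 61 probes were higher and 36 lower.

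The change from the starting state was also compared between acclimated and fresh plants. At 2 h, 971 probes changed differently from their own starting point, 473 more upward and 498 more downward in acclimated plants. CUST_14227_PI425357171 and CUST_13131_PI425357171, which share 35 bases, had the largest upward differences, 7.53 (SE 1.13) and 7.45 (SE 1.12) on the log2 scale (adjusted p = 0.000604 and 0.000606). CUST_14227_PI425357171 went from 1.88 ± 0.34 in control to -2.10 ± 0.87 in fresh plants at 2 h, and from -1.51 ± 0.47 in rehydrated plants to 2.04 ± 1.01 in acclimated plants. CUST_12888_PI425357171 and CUST_5700_PI425357171 had downward differences of -5.33 (SE 1.19) and -5.23 (SE 1.26). With slide as a block 927 probes were called, with row 811 and within the first row 689. The count was 573 without acclimated 2 h replicate 2 and 613 without control replicate 1. Of 100 random relabellings of the 12 arrays, which also exchange watered with dried plants, 13 gave as many probes. When only drying-history labels were exchanged within a water state, a test chosen afterwards, 1 of 100 did, the real split (highest other 554). Spike-in scaling turned 48.7% upward differences into 83.5%.

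At 48 h, 1671 probes differed, 834 upward and 837 downward. CUST_14227_PI425357171 and CUST_13131_PI425357171 again led the upward differences, at 5.10 (SE 1.13) and 4.98 (SE 1.12). CUST_13392_PI425357171 and CUST_12650_PI425357171 led the downward ones, at -7.11 (SE 1.27) and -7.06 (SE 1.26), since their level was already high in rehydrated plants and ended at 6.89 ± 0.19 and 6.86 ± 0.16, against 6.15 ± 0.81 and 6.18 ± 0.87 in fresh plants. As many probes were called in 16 of 100 random relabellings, and in 1 of 100 exchanges of drying-history labels within a water state, the real one (highest other 1252). Slide as a block gave 1202 calls and row 1708, and spike-in scaling moved the count to 1049. Upward differences were 49.9% of the calls and 33.5% with normexp background correction.

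On the rapid-drying score, where control averaged 0 and fresh plants at 48 h 1, fresh plants at 2 h reached 0.553 ± 0.038 (SD, n = 3) and acclimated plants 0.678 ± 0.015, while rehydrated plants lay at 0.144 ± 0.016, against 0.0321 for simulated unchanged plants. The 3 acclimated 2 h arrays were all above the 3 fresh 2 h arrays (exact permutation p = 0.1, two-sided, the smallest the design allows), by 0.125 on average, 0.0909 within the first slide row, which holds 1 fresh 2 h array, and 0.130 within the second, which holds 1 acclimated 2 h array. At 48 h acclimated plants scored 1.03 ± 0.037. Their difference from fresh plants, 0.029, was smaller than the spread of the fresh arrays (SD 0.14, exact permutation p = 0.9). The probes, signs and scale of this score come from the same fresh 48 h arrays, which may raise their score. The permutation did not repeat that choice. On the slow-drying score, where slow 14 d plants averaged 1, acclimated plants at 48 h reached 0.678 ± 0.083 and fresh plants 0.442 ± 0.094, a difference of 0.235 (exact permutation p = 0.1, the smallest possible). Before rapid drying, rehydrated plants already lay 0.140 above control on this score (SD 0.077, n = 3; exact permutation p = 0.1), with replicate 2 at 0.230 and the others at 0.0951 and 0.0958, and simulated unchanged plants lay at 0.0234. Both acclimated groups were on slide 3, and fresh arrays on slides 1 and 2, so no slide holds both.

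**Figure D4:**
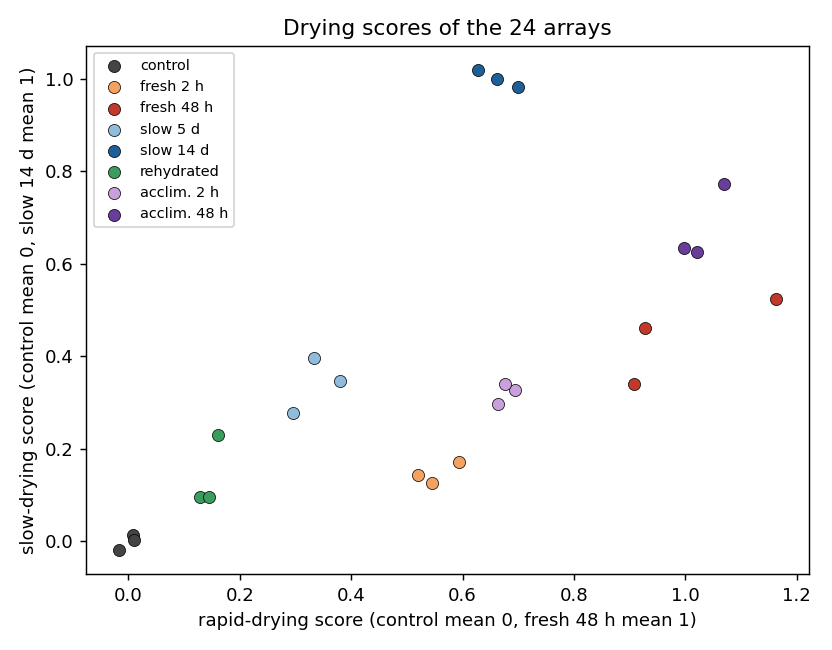
Rapid-drying score (x axis, control mean 0 and fresh 48 h mean 1) and slow-drying score (y axis, control mean 0 and slow 14 d mean 1) of the 24 arrays, 1 point per array, coloured by group. Acclimated 48 h arrays average 1.03 on the x axis and 0.678 on the y axis, where fresh 48 h arrays average 0.442.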

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

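Most tests in this part were set before their results were seen; the comparison of the rehydrated with the slow-drying changes, the positions of single fresh 48 h arrays, the drying scores and the simulations of unchanged positions and scores were chosen afterwards.

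The response to rapid drying differed between acclimated and fresh plants, tested as the difference of the responses, at 971 probes after 2 h and at 1671 after 48 h. When the 12 arrays of each test were relabelled at random, 13 of 100 splits gave as many probes at 2 h, the highest other giving 2570, and 16 of 100 at 48 h, the highest other giving 5345, so these splits do not exclude chance. Those splits also exchange watered with dried plants, and counts several times the real one point to a structure of the samples. When only the labels of drying history were exchanged within a water state, 1 of 100 splits, the real one, gave as many at either time, and the highest others gave 554 and 1252. That second test was chosen after the first result was seen.

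The 77 negative-control spots, which take no part in the comparisons, varied most on acclimated 48 h replicate 1, with an SD of 57.5 units against 2.52 to 3.04 on the 3 control arrays. That array lay in the second slide row, where SDs were 4.45 to 57.5 (median 21.8). The control arrays lay in the first, where they were 2.30 to 5.22. The explanation was not tested.

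Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05; in all of them 1 split, the real one, reached the real count. The real count and the highest other were 4399 and 0 for fresh 2 h, 6183 and 2 for fresh 48 h, 4798 and 0 for slow 5 d, 6822 and 1 for slow 14 d, 2047 and 0 for rehydrated, 5007 and 0 for acclimated 2 h, and 6753 and 0 for acclimated 48 h plants, each against control. Against rehydrated plants they were 3943 and 6 for acclimated 2 h and 6820 and 3 for acclimated 48 h. For acclimated against fresh plants they were 1232 and 244 at 2 h and 2220 and 16 at 48 h, and for slow 14 d against fresh 48 h 6526 and 361.

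Rehydrated plants differed from control at 2047 probes, at 86 with slide as a fixed block and at 1541 with slide as a random block. The random block also uses differences between slides, so it does not separate slide from group. The fixed block rests on single arrays that link slides. Of the main calls that it could test, 96.1% kept their direction. Whether a drying response was not fully reversed stays open, since the comparisons share the control arrays and both cross slides. Of 1402 probes called in both rehydrated and slow 14 d plants, 77.7% went the same way. Shared calls were 504 rises and 586 falls, against 255 and 342 for independent lists. The covariance of the changes was 0.62, against 0.11 in simulations of unchanged groups, so shared controls alone gave less than was seen. The correlation was 0.34, and the 0.49 simulated holds for noise alone, so the 2 are not compared. An effect of slide 3 would leave little of the shift in the rehydrated array on slide 2, where the slope on the shift of the slide 3 arrays was 0.585 (bootstrap SD 0.0229 over 1252 probes). A difference of slide 1 from the others would also appear within fresh 48 h plants, where the slope was -0.0124 (SD 0.0161). Both values met the bounds set beforehand against these explanations, but each rests on 1 array, which excludes nothing, so slide and group cannot be told apart here.

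Acclimated plants dried for 48 h lay nearer to slow 14 d plants than fresh 48 h plants did, at a position of 0.252 from fresh 48 h (0) to slow 14 d (1; 0.201 to 0.319 per acclimated array, over 6849 probes), against 0.000106 on average in simulations without a change. Single fresh 48 h arrays lay between -0.140 and 0.180 when measured from the others of their group, so the margin over the highest is small, and leaving out fresh 48 h replicate 1 or 3 gave positions of 0.302 and 0.188. The latter is also the value with second-row arrays only, where the acclimated arrays (0.134 to 0.256) overlap that spread, so row background stays open. With the course from fresh 2 h to fresh 48 h removed the position was 0.255 (0.205 to 0.321, fresh arrays up to 0.194). It hardly changed, so straight-line progress along that course accounts for little of the position. The margin over single fresh arrays is small, and the removal was not repeated with second-row arrays only. Progress along a course that bends was not tested. Fresh 48 h replicate 3, the one on slide 2 with the slow-dried arrays, lay at -0.136, but 1 array excludes nothing about slide 2, and an effect of slide 3, which holds all acclimated arrays, was not tested for this position and stays open, as does an effect of the earlier drying cycle.

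Acclimated 2 h plants scored 0.125 higher than fresh 2 h plants on the rapid-drying response. Rehydrated plants scored 0.144 above control before drying began. That met the bound set for a head start, which asked for at least 0.125. Simulated unchanged plants, added after that value was seen, also scored 0.0321 above the shared controls. With separate control arrays for choosing the probes and for the baseline the value was 0.125 to 0.145. Whether the difference reflects a head start stays open. Within the first slide row the difference was 0.0909 and within the second 0.130, both over the bound set against row background, but each has 1 array on one side, so row background stays open. The rehydrated arrays on slide 3 scored 0.0241 above the one on slide 2, under the bound set against an effect of slide 3, but that rests on 1 array and the slide cannot be told apart from the group. The score of rehydrated plants is itself measured across slides, so it is no independent evidence of a biological cause.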

How the results depend on the processing

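Tests with slide row as a block, with slide and slide row as blocks, within a slide or a row and with a common signal floor were chosen after the results were seen; the other alternatives were set before the data were examined.

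Of 242 counts of changed probes under alternatives other than leaving out 1 array, 205 stayed within 1.5 times and 37 did not; calls of named probes were lost 28 times, and no direction reversed. The cause of each move below was not tested, except that stricter thresholds call fewer probes by construction.

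The counts with slide as a fixed block were 2998 for slow 5 d, 86 for rehydrated, 1353 for acclimated 2 h and 3357 for acclimated 48 h plants against control, and 82 and 372 for acclimated against fresh plants at 2 h and 48 h. Slide as a random block, which also uses differences between slides, kept the counts within 1.5 times. It gave 1541 for rehydrated against control, and 839 and 1751 for acclimated against fresh plants. With slide and slide row they were 2611 for slow 5 d, 3496 for slow 14 d, 31 for rehydrated, 941 for acclimated 2 h and 1706 for acclimated 48 h against control, and 331 and 97 for acclimated against fresh plants. First-row arrays alone gave 3405 for rehydrated against control and 239 for acclimated against fresh plants at 2 h. Second-row arrays alone gave 650 and 3615 for acclimated 2 h and 48 h against rehydrated plants, and 171 and 211 against fresh plants. A lone array of a group was assumed to vary like the other groups. The groups compared alone gave 109 for acclimated against fresh plants at 48 h. Spike-in scaling gave 1479 there and 1049 for the difference of the 48 h responses.

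At 2-fold or more the counts against control were 2444 for fresh 2 h, 4086 for fresh 48 h, 2995 for slow 5 d, 1215 for rehydrated and 2864 for acclimated 2 h plants. They were 2291 for acclimated 2 h against rehydrated plants, and 770 and 1289 for acclimated against fresh plants at 2 h and 48 h. At an adjusted p below 0.01 they were 2784 for fresh 2 h and 788 for rehydrated against control, 2434 for acclimated 2 h against rehydrated plants, 465 and 1074 for acclimated against fresh plants, and 388 and 655 for the differences of the 2 h and 48 h responses. Probes changed the same way and 2-fold in both comparisons with control numbered 1831 for fresh 2 h and 48 h, 1755 for slow 5 d and 14 d, 2170 for fresh 48 h and slow 14 d, 3281 for fresh and acclimated 48 h, 1662 for fresh and acclimated 2 h, and 569 for slow 14 d and rehydrated plants.

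Leaving out 1 array at a time gave 3470 to 3712 for fresh 2 h, 5304 to 6246 for fresh 48 h, 3933 to 4268 for slow 5 d, 6233 to 6609 for slow 14 d, 1137 to 1983 for rehydrated, 4075 to 4536 for acclimated 2 h and 6132 to 6360 for acclimated 48 h plants against control. Against rehydrated plants it gave 3045 to 3653 for acclimated 2 h and 6190 to 6428 for acclimated 48 h, and 5916 to 6594 for slow 14 d against fresh 48 h. For acclimated against fresh plants it gave 583 to 1166 at 2 h and 1262 to 2581 at 48 h, and for the difference of responses 573 to 978 at 2 h and 1121 to 1983 at 48 h. Counts moved by over 1.5 times in 12 of these 96 fits. For rehydrated against control these were without control replicates 1, 2 and 3 (1196, 1221 and 1137) and rehydrated replicate 2 (1139). For acclimated against fresh plants at 2 h they were without fresh replicates 2 and 3 (583 and 700) and acclimated replicates 1 and 2 (729 and 604). At 48 h they were without fresh replicate 3 (1262) and acclimated replicate 3 (1392). For the difference of the 2 h responses they were without control replicate 1 (613) and acclimated 2 h replicate 2 (573).

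With the replicate number as a replicate block the counts stayed within 1.5 times, for example 1802 for rehydrated against control and 1051 and 2036 for acclimated against fresh plants at 2 h and 48 h. The numbers do not pair the arrays: deviations from the group means correlated at -0.33 to 0.24, over 0.1 in 4 of 28 pairs per number, and 2 arrays per number were closest to their own number.

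Scaling moved the median log2 change of all probes by over 0.1 in several comparisons, for example from -0.06 to 0.29 for slow 5 d against control with spike-in spots. The larger part of the calls, higher or lower, turned under at least 1 alternative in each of the 14 comparisons, so the balance of calls is not settled. Alternatives for gene lists were not run because no probe is named. Signal over background limits the dim probes: 55.4% to 83.5% of probes per array were well above it, fewest in the second slide row. Not all probes changed against control were well above background on every array compared. Those that were numbered 3706 for fresh 2 h, 5208 for fresh 48 h, 4461 for slow 5 d and 5180 for slow 14 d plants. They numbered 1708 for rehydrated, 4170 for acclimated 2 h and 5264 for acclimated 48 h plants.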

Other observations

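The summaries of probe groups in this part were chosen after the results were seen, as were the named probes whose levels are set out below.

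In all 6 drying comparisons with control, 468 probes were higher and 424 lower, and in the 3 at the lowest water content 1682 were higher and 1590 lower. Independent lists would share 1.46 and 3.14, and 231 and 295. In 20 simulations of unchanged groups, which have almost no calls, 0 probes were shared. These comparisons share the control arrays, so part of the shared calls rests on the same values.

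Of the 462 probes that were higher after slow 14 d and lower after fresh 48 h drying, acclimated plants at 48 h followed the rapid direction at 216 and the slow direction at 21, with 225 not called. Their median log2 change from control was -0.77 in fresh, -0.41 in acclimated and 0.79 in slow-dried plants. Of the 345 that were lower after slow and higher after rapid drying, 145 followed the rapid and 26 the slow direction, and 174 were not called, with medians of 1.37, 0.52 and -1.67. Among probes well above background on all arrays the numbers were 190 and 21 of 410, and 93 and 16 of 208.

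Several of the named probes took courses of their own over the groups. CUST_13846_PI425357171 lay at 2.43 ± 0.14 in control (SD, n = 3), -1.74 ± 0.71 in fresh 2 h, -1.03 ± 0.92 in slow 5 d and 5.43 ± 0.19 in slow 14 d plants. CUST_5691_PI425357171 lay at -4.89 ± 0.42 in control, 2.79 ± 1.16 in fresh 48 h and 3.60 ± 0.99 in acclimated 48 h plants, and at -5.59 ± 1.15 in slow 14 d plants, where 2 arrays were well above background. CUST_12888_PI425357171 lay at -0.22 ± 0.27 in control, -4.66 ± 0.41 in slow 14 d plants and 3.90 ± 0.26 after rewatering.

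Probes switched on from below background in control, at least 2-fold, numbered 38 in fresh 48 h, 34 in slow 5 d, 23 in slow 14 d and 34 in acclimated 48 h plants. Of the 38, 15 were also on in slow 14 d plants; of the 34 in acclimated 48 h plants, 17 were on in slow 14 d and 19 in fresh 48 h plants. Some probes were switched off and called with a lower bound on the fall of at least 2-fold. They numbered 4 in fresh 48 h, 72 in slow 5 d, 382 in slow 14 d and 136 in acclimated 48 h plants. All slow 14 d and acclimated 48 h arrays, and 2 fresh 48 h arrays, lay in the second slide row, where fewer probes were detected. These numbers are therefore not compared between groups.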
